A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

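Gene expression was measured on 10 two-colour arrays. Per the labels, cells were grown in rich medium at 28 °C to an absorbance between 0.6 and 0.8, 30 ml of culture was harvested, and cDNA was made from 8 µg of total RNA and coupled to Cy3 or Cy5. The design text lists 6 RNA samples, wt and 5 mutants, with a dye swap of each, so the 2 arrays of a mutant were treated as technical repeats of 1 extract. The deposited values are log ratios, taken as log2, of mutant over wt. The authors left out small spots, under 120 µm across, and spots under 150 intensity units in Cy3 and Cy5, per the labels. The scanner, background correction, normalization, software and log base are not given in the sources used here. Base 10 was excluded by the extreme values, and the natural logarithm was not. The direction was taken from the values and labels together: dye-swapped arrays of a mutant correlated positively, with r between 0.19 and 0.51 across genes, and PTC1, PTC3 and PTC5 were negative on both arrays of their own mutant, so the sign had already been turned there. PTC2 was negative on the 1 ptc2 array that measured it. PTC4 had no value in ptc4, so there the direction was taken from the label alone; the positive correlation of its arrays shows only that both have the same direction. The signal intensities behind the ratios were not used here, so dim genes could not be told from bright ones.

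Gene symbols came from a RefSeq gene table of assembly R64. Of 6212 identifiers 5662 matched a locus tag and 550 did not and kept the deposited name. No genome build is named for the array, so no coordinates are given. The number of values per array lay between 4195 and 4802, and 927 identifiers had no value on any array. Values were used as deposited, without further normalization. The median SD of the 2 arrays of a mutant lay between 0.12 and 0.19, and the 2 arrays had the same sign for between 50.0% and 61.6% of genes.

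For each mutant against wt, the 2 arrays were averaged. With 1 extract per strain there is no test, so genes were taken by size: a mean log2 ratio of at least 1 in size with both arrays at least 1.5-fold in that direction. For tests, limma 3.58.1 in R 4.3.3 was fitted to the 5 per-mutant means of the 3606 genes present on all arrays, each mutant against the mean of the other 4, with 3 residual degrees of freedom, and the mean of the 5 against 0, with 4. Benjamini-Hochberg adjusted p-values of at most 0.05 were called. Since no label says that extracts came from separate cultures beyond the strain, these p-values measure the spread between these samples. Gene lists, 29 of them and 4 lists of markers, were compared with wt by the median over members measured on both arrays and its percentile among 10000 random lists of the same size drawn from all measured genes, where at least 5 members were measured, and between mutants by camera with a preset correlation of 0.01, repeated with the estimated correlation. The results of 1 of the lists are not reported here, though counts over all lists include it. A further 6 lists were chosen after seeing the data and appear only in the closing observations. Genes named in the text are the 5 deleted genes, for each mutant against wt up to 12 higher and 12 lower genes by size, for each mutant against the others up to 8 and 8 by adjusted p, for the set up to 6 and 6, and up to 4 members per list by size. The design, tests, lists and naming rule were chosen before the data were examined.

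Array numbers coincide with dye orientation. The difference between a mutant's 2 arrays correlated between mutants in all 10 pairs, with r between 0.16 and 0.66, so the numbers were taken to pair the arrays. The alternatives were centring each array, other rules on missing spots and on size, robust moderation, arrays as samples with and without the array number as a block, and leaving out each array number or mutant.

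The fits were checked on simulated data for 3606 genes with 200 genes changed in ptc1. Simulated extracts deviated as ptc2 to ptc5 differ from each other, which includes genotype effects, so counts of unchanged genes called do not measure chance alone. Of genes changed by a log2 of 1, 1.5 and 2, the test against the other 4 mutants recovered 82.1%, 98.5% and 98.5% and called 8 unchanged genes. The size rule recovered 52.2%, 98.5% and 98.5% and called 13 unchanged genes. The test of the 5 mutants as a set called 139 unchanged genes when the wt extract deviated like a mutant extract and 0 when it did not. Camera gave 0% of unshifted lists of 20 genes a p under 0.05. The simulated genes were independent of each other, while estimated correlations within the real lists reached 0.89. This check therefore does not cover false calls that the preset correlation of 0.01 can give for genes that vary together.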

Results

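Transcript levels were compared between wild-type (wt) budding yeast, Saccharomyces cerevisiae, and 5 mutant strains named ptc1 to ptc5 after genes of the type 2C protein phosphatase family, enzymes that remove phosphate from serine and threonine residues of other proteins. Each mutant RNA was hybridised against wt RNA on 2 two-colour arrays, with the mutant in Cy5 on array number 1 and in Cy3 on array number 2, so that 10 arrays covered 6 RNA samples. The arrays held between 4195 and 4802 values for 6212 listed open reading frames, and 3606 frames had a value on all 10 arrays. The values are log ratios of mutant over wt, read as log2; no label states the base, and if it were the natural logarithm all folds given here would be too small. Each strain was taken to be represented by 1 RNA extract, since the design text lists 6 RNA samples with a dye swap of each. The titles number the 2 arrays of a mutant as experiments and do not rule out separate extracts. The SD given beside a mean covers the 2 dye-swapped arrays of a mutant, taken as the same extract (n = 2, technical), and no difference between a single mutant and wt has a replicate test. The number of arrays limits the precision of every value.

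The deleted genes were examined first. In ptc1, the log2 ratio of PTC1 was −1.97 and −1.86 on the 2 arrays. In ptc3, that of PTC3 was −8.79 and −6.91. In ptc5, that of PTC5 was −2.43 and −2.34. PTC2 had a value on only 1 ptc2 array, where the log2 ratio was −7.86. PTC4 had no value on either ptc4 array and only 1 value elsewhere, −0.34 on the first ptc1 array, so the identity of the ptc4 strain could not be checked from its deleted gene. PTC1 lay between −0.45 and 0.42 on the 8 arrays of the other mutants, PTC3 between −0.28 and 0.28 on its 8, PTC5 between −0.16 and 0.71, and PTC2 between −0.14 and 0.24 on the 7 arrays of other mutants that measured it.

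**Figure D1:**
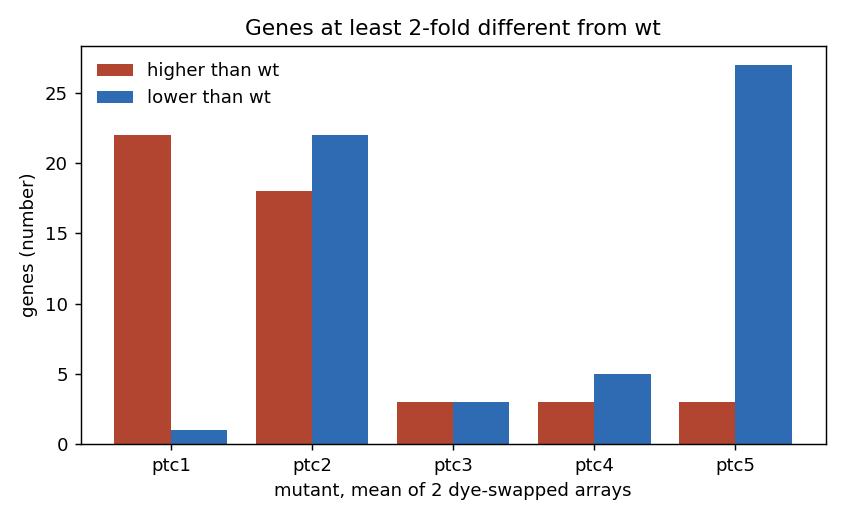
Number of genes (vertical axis) at least 2-fold higher or lower than wt in the mean of 2 dye-swapped arrays, for each mutant (horizontal axis). The bars for ptc1 are 22 higher and 1 lower, and those for ptc5 are 3 higher and 27 lower.

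The first comparison asked which transcripts differed between ptc1 and wt. The genes furthest above wt included members of the cell wall integrity list and small heat shock genes. KDX1, a kinase-like gene of the cell wall integrity pathway, had a mean log2 ratio of 2.76 ± 0.0035 (SD, n = 2 arrays), a 6.78-fold difference. YPS3, a cell-surface aspartyl protease, was at 1.92 ± 0.12, and SED1, PRM5 and CRH1, also of the cell wall integrity list, were at 1.41 ± 0.50, 1.34 ± 0.16 and 1.25 ± 0.028. The small heat shock genes HSP26 and HSP12 were at 1.61 ± 0.048 and 1.497 ± 0.12. CIT2, the peroxisomal citrate synthase, was at 1.47 ± 0.16. YIR042C, SRL3, CRG1 and AFR1 were at 1.78 ± 0.35, 1.76 ± 0.091, 1.59 ± 0.033 and 1.40 ± 0.023. By the size rule, a mean of at least 2-fold with both arrays at least 1.5-fold in that direction, 22 genes were higher, and the 1 lower gene was PTC1 itself at −1.91 ± 0.081. In simulated data over 3606 genes, with extracts that deviated as ptc2 to ptc5 differ from each other, this rule called 13 unchanged genes. Those differences include genotype effects, such as that on PTC3 in ptc3, so the 13 does not measure chance calls.

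Among gene lists fixed before the data were examined, the cell wall integrity (Slt2/Rlm1) genes had a median log2 ratio of 0.72 in ptc1, at percentile 100 among 10000 random lists, with 22 of 24 measured members above 0 and 9 meeting the size rule. Random lists hold unrelated genes, whereas members of a list can vary together, so such a percentile describes these arrays and does not measure chance. Calcineurin/Crz1 genes had a median of 0.36, with 12 of 14 members above 0, led by CRH1, then GSC2 at 0.57 ± 0.07 and KRE6 at 0.55 ± 0.01, both genes of glucan synthesis. General stress (Msn2/4) genes had a median of 0.26, with 19 of 24 above 0 and 2 meeting the size rule, and osmostress (Hog1) genes one of 0.13 with 7 of 13 above 0 and 1 meeting it. Nitrogen catabolite repressed genes had a median of 0.35, led by the amino acid permease genes GAP1 at 1.15 ± 0.19 and AGP1 at 0.75 ± 0.06. Components of the HOG and cell wall integrity pathways had a median of 0.09, led by the kinase gene SLT2 at 1.21 ± 0.15 and the phosphatase gene PTP2 at 0.84 ± 0.11. Ribosomal protein genes had a median of −0.31 with 118 of 120 members below 0, histone genes −0.33 with 10 of 10 below 0, and glycolysis genes −0.23 with 15 of 16 below 0, although on the first and second arrays alone the glycolysis median was 0.07 and −0.51 and the ribosomal protein median −0.155 and −0.447. Iron (Aft1) genes had a median of −0.15, led by FET3 at −0.56 ± 0.06, but on the first array alone the median was −0.073, inside the middle 95% of random lists. Hexose transporter genes had a median of 0.22 over 5 measured members, led by HXT6 at 0.65 ± 0.26. The medians of the respiratory chain genes, 0.08, and of the amino acid biosynthesis (Gcn4) genes, 0.07, also lay outside the middle 95% of random lists, but on the second array alone they were −0.0070 and −0.04. On the second array alone the medians of the osmostress genes, 0.098, pathway component genes, 0.056, and hexose transporter genes, 0.19, also lay inside it.

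**Figure D2:**
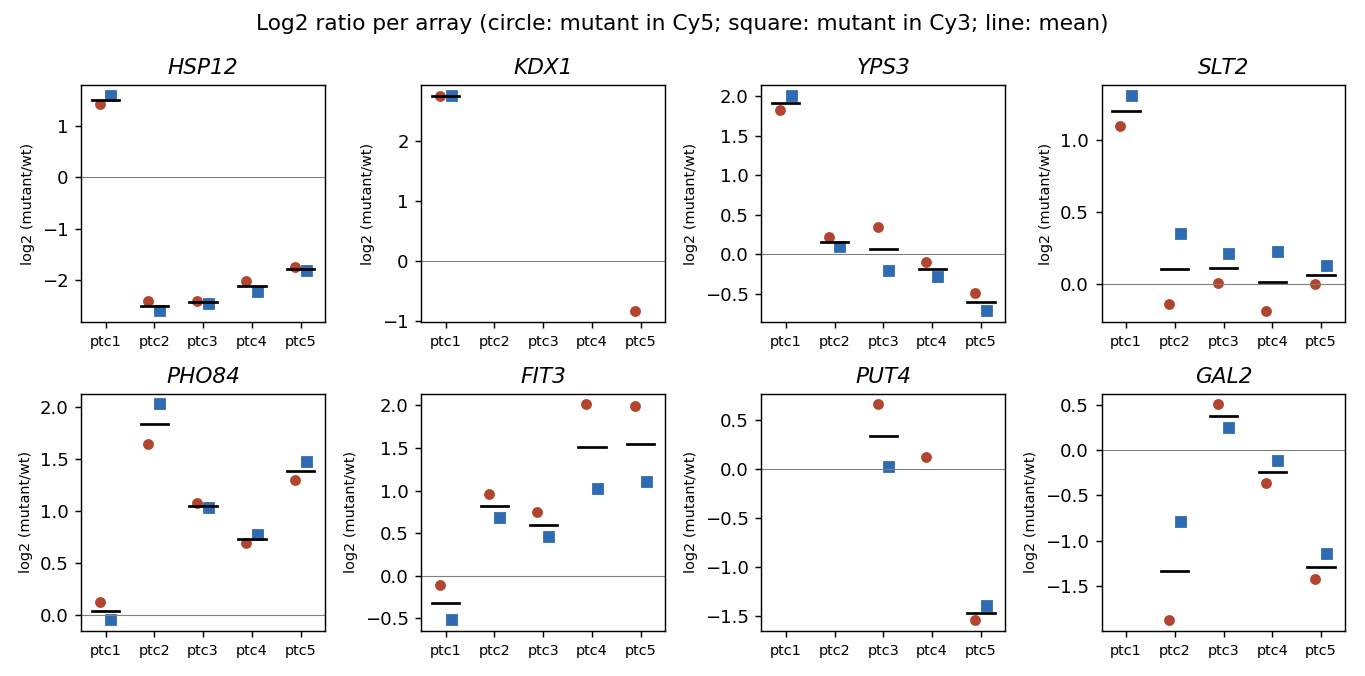
Log2 ratio of mutant over wt (vertical axes) on each array for 8 genes, by mutant (horizontal axes); circles are arrays with the mutant in Cy5, squares those with the mutant in Cy3, and the line is their mean, drawn where both arrays gave a value. HSP12 has a mean of 1.497 in ptc1 and −2.50 in ptc2, and an empty position means that the array gave no value.

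The mutant profiles were then compared with each other, which removes the wt RNA common to all arrays. In these comparisons rose and fell mean higher or lower in the named mutant than in the mean of the other 4. Such a difference can stem from either side. HSP12 rose by 3.70 on the log2 scale in ptc1 against the mean of the other 4 mutants (limma on the 5 per-mutant means, adjusted p = 4.63e-05). The cell wall genes YPS3, SED1 and PST1 rose by 2.06, 1.56 and 1.16, and the cell wall integrity kinase gene SLT2 rose by 1.14. MSC1, SOL4 and YOR289W rose by 1.38, 1.23 and 1.16. Besides PTC1, which fell by 1.92, the siderophore transporter gene SIT1 fell by 1.38 and the metalloreductase gene FRE7 fell by 0.97. Over wt, SIT1 was at −0.50 in ptc1 and at 0.86, 0.70, 1.03 and 0.95 in ptc2 to ptc5, further from 0 in each of these. RKI1, the ribose-5-phosphate isomerase of the pentose phosphate pathway, fell by 0.87, as did DML1, and YJL218W fell by 0.88. The frames YJR026W and YML045W, parts of Ty retrotransposons whose near-identical copies can share hybridisation, fell by 0.99 and 1.02 and count as uncertain. The adjusted p-values of these 16 genes lay between 4.63e-05 and 0.015.

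In total 62 genes were higher and 61 lower in ptc1 than in the other 4 mutants, out of 3606 tested. The lower genes included all measured Ty1 and Ty2 frames, near-identical copies that can share hybridisation and may not be separate results. The limma test has 3 residual degrees of freedom and assumes that ptc1 varies like the other mutants. The count was 56 over genes with at least 1 array per mutant, 44 without ptc4 and 62 without ptc5, and with single arrays it was 7 without array number 1 and 46 without array number 2. With arrays as samples and the array number as a replicate block it was 395, a fit whose spread is technical if the 2 arrays of a mutant share an extract.

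Of the cell wall integrity genes, 11 of 18 tested rose in ptc1 against the other mutants over all genes tested, and 13 when adjusted over the list alone. Their median difference was 0.64, and camera gave the list an adjusted p = 4.54e-17 with a preset correlation but an adjusted p = 0.990 with an estimated correlation. General stress genes had 10 of 21 risen, 13 adjusted over the list alone, with a median difference of 0.60 and an adjusted p = 7.97e-17 with the preset correlation, but an adjusted p = 0.990 with an estimated correlation. Of the iron genes 6 of 16 fell, 8 adjusted over the list alone, and of the ribosome biogenesis genes 6 of 21 fell, with 16 lower and 1 higher adjusted over the list alone. No single ribosomal protein gene of 106 passed over all genes tested, while 63 were lower adjusted over the list alone, with a median difference of −0.38. Adjusted over the list alone, 12 of 19 respiratory chain genes, 4 of 11 calcineurin/Crz1 genes and 3 of 8 nitrogen catabolite repressed genes rose, of which 2, 0 and 1 passed over all genes tested. Likewise 13 of 15 glycolysis genes and 5 of 12 phosphate genes fell adjusted over the list alone and 0 of either over all genes tested, and of 13 osmostress genes 5 rose and 1 fell, with 4 risen over all genes tested. Against wt, some of these lists were shifted mainly in the other 4 mutants. Uncentred phosphate, ribosome biogenesis and respiratory chain medians were 0.07, −0.07 and 0.08 in ptc1. In the others they ran from 0.25 to 0.75, 0.23 to 0.47 and −0.46 to −0.27. Uncentred iron medians were −0.15 in ptc1 and ran from 0.14 to 0.34 in the others. No list call held with an estimated correlation, and 43 of 140 tests of a list in a mutant passed with the preset one. The repeat with the estimated correlation has 3 residual degrees of freedom and could hardly pass any list. Osmostress genes in ptc1 lost their call at an estimated correlation of 0.026, near the preset 0.01. Other lists reached 0.89, so calls with the preset one are not secure.

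No gene passed in ptc2 or ptc4 in this limma test. Their deleted genes PTC2 and PTC4 lacked values on some arrays and were not among the genes tested. Besides the main fit, the other limma fits gave ptc2 between 0 and 53 genes and ptc4 between 0 and 2. In ptc3 the 1 gene that passed was PTC3, which fell by 7.88 (limma, adjusted p = 3.32e-08), and in ptc5 it was PTC5, which fell by 2.44 (limma, adjusted p = 0.0040). With arrays as samples and the replicate block, the counts were 53 in ptc2, 21 in ptc3, 2 in ptc4 and 21 in ptc5.

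The size rule took 4 of 13 phosphate (Pho4) genes as higher in ptc2 than in wt and 2 of 25 general stress genes as lower. The second ptc2 array had a median log2 ratio of 0.23 over all genes, against medians between −0.029 and 0.035 on the other 9 arrays. PHO84, the high-affinity phosphate transporter, had a mean log2 ratio of 1.84 ± 0.27 (SD, n = 2 arrays). The acid phosphatase genes PHO12 and PHO11, whose near-identical sequences can share hybridisation, were at 1.33 ± 0.21 and 1.29 ± 0.27, and VTC3, of the vacuolar polyphosphate polymerase, was at 1.21 ± 0.55. SGE1, NOP12 and AVO2 were at 1.37 ± 1.09, 1.15 ± 0.18 and 1.11 ± 0.16. The Ty frames YAR010C, YJR028W, YJR026W, YML045W and YML040W were between 1.10 and 1.22. HSP12 was at −2.50 ± 0.14, a 5.66-fold lower level, and the stress genes HSP30 and SPI1 were at −1.38 ± 0.41 and −1.29 ± 0.023. The galactose permease gene GAL2 was at −1.34 ± 0.76, YNL034W at −1.53 ± 0.78 and the isomaltase gene IMA3 at −1.23 ± 0.086. The seripauperin genes PAU14, PAU1, PAU12, PAU24, PAU15 and PAU11, members of a near-identical family, lay between −1.40 and −1.21. By the size rule 18 genes were higher and 22 lower, or 11 and 12 with the PAU, IMA and Ty families counted once each. With each array centred on its median 7 were higher and 27 lower, and on the second array alone 180 genes differed at least 2-fold.

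Relative to each array's median, the phosphate (Pho4) genes in ptc2 had a median of 0.62, ribosome biogenesis genes 0.34, iron genes 0.21, glycolysis genes 0.16, proteasome genes 0.12 and ribosomal protein genes 0.09. The single arrays disagreed on the last of these lists: the uncentred ribosomal protein median was 0.29 on the first array, whose median over all genes was 0.025, and 0.11 on the second, below the 0.23 of all genes there. The glycolysis median was 0.395 on the first array and 0.27 on the second, close to that of all genes. On the same centred scale the general stress genes had a median of −0.44, the respiratory chain and ATP synthase genes −0.40, the osmostress genes −0.31 and the calcineurin/Crz1 genes −0.15. The uncentred calcineurin/Crz1 median was −0.03, with −0.06 on the first array and 0.05 on the second. All of the centred medians in this paragraph lay outside the middle 95% of 10000 random lists, but the calcineurin/Crz1 median lay inside it on each array alone, and the proteasome and glycolysis medians on the second.

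In ptc3, 3 genes were higher than wt by the size rule and 3 were lower. In simulated data this rule called 13 unchanged genes. The simulated deviations include genotype effects, PTC3 in ptc3 among them, so that number does not say how many calls chance would give here. The higher genes were PHO11, PHO12 and PHO84, at 1.22 ± 0.20, 1.22 ± 0.18 and 1.06 ± 0.038 (SD, n = 2 arrays). Besides PTC3 at −7.85 ± 1.33, the lower genes were HSP12 at −2.42 ± 0.047 and HOR7 at −1.03 ± 0.24, both of which respond to osmotic stress. General stress genes had a median log2 ratio of −0.50, with 24 of 26 below 0, led by HSP12 and then PGM2 at −0.98 ± 0.13. Respiratory chain genes had a median of −0.34 with 25 of 25 below 0, TCA cycle genes −0.20 with 12 of 13 below 0, osmostress genes −0.19 and G1/S cell cycle genes −0.13, the last inside the middle 95% of random lists on the first array alone. Phosphate genes had a median of 0.37 with 13 of 14 above 0. Hexose transporter genes were at 0.27, ribosome biogenesis genes at 0.23, and calcineurin/Crz1, zinc (Zap1) and iron genes each at 0.16, but on the second array alone the calcineurin/Crz1 and zinc medians were 0.0050 and 0.0265. On either array alone 18 genes differed at least 2-fold, against 6 in the mean.

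In ptc4, BSC1, FIT3 and SIT1 were higher than wt, at 1.83 ± 0.041, 1.51 ± 0.70 and 1.03 ± 0.12 (SD, n = 2 arrays); FIT3 and SIT1 act in the uptake of iron bound to siderophores. HSP12, HSP30, SPI1, SOL4 and MSC1 were lower, at −2.12 ± 0.16, −1.33 ± 0.26, −1.22 ± 0.36, −1.03 ± 0.084 and −1.02 ± 0.076. General stress genes had a median log2 ratio of −0.46 with 23 of 24 below 0, and respiratory chain genes one of −0.45 with 20 of 20 below 0, led by QCR9 at −0.74 ± 0.16. Osmostress genes were at −0.28, TCA cycle genes at −0.26 with 12 of 12 below 0, and histone genes at −0.19, the last at −0.12 on the first array alone, inside the middle 95% of random lists. Ribosome biogenesis genes had a median of 0.39, with 0.24 on the first array alone, led by DBP2 at 0.70 ± 0.17. Phosphate genes were at 0.25 with 13 of 13 above 0, iron genes at 0.19 and zinc genes at 0.17, the last at 0.076 on the second array alone. On the second array alone 31 genes differed at least 2-fold, against 8 in the mean. The 13 unchanged genes that the size rule called in simulated data do not measure chance for these 8 either, since the simulated deviations include genotype effects.

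In ptc5, 3 genes were higher than wt by the size rule and 27 were lower. FIT3, PHO84 and BSC1 were higher, at 1.55 ± 0.63, 1.39 ± 0.12 and 1.30 ± 0.13 (SD, n = 2 arrays). PTC5 was at −2.38 ± 0.061, HSP12 at −1.78 ± 0.059 and HSP30 at −1.73 ± 0.028. The proline permease gene PUT4 was at −1.47 ± 0.10, GAL2 at −1.29 ± 0.20, RRT12 at −1.31 ± 0.35, and YLR465C and YHL049C at −1.51 ± 0.16 and −1.29 ± 0.26. PAU14, PAU15, PAU21 and PAU24 lay between −1.33 and −1.29. Respiratory chain genes had a median log2 ratio of −0.46 with 20 of 20 below 0, general stress genes −0.36 with 20 of 22 below 0, nitrogen catabolite repressed genes −0.20 with 9 of 10 below 0, osmostress genes −0.15 and calcineurin/Crz1 genes −0.11. On the second array alone the osmostress and nitrogen catabolite medians were −0.37 and −0.36. The calcineurin/Crz1 median was −0.0075 and −0.15 on the 2 arrays, inside the middle 95% of random lists on each. Type 2C phosphatase genes were at −0.21 and the pyruvate dehydrogenase complex and regulator genes at −0.19. Both lists hold the deleted PTC5 itself and also PTC6, at −0.40 ± 0.12. On the first array alone the pyruvate dehydrogenase median was −0.081, inside the middle 95% of random lists, and the type 2C phosphatase median lay inside it on each array alone. Ribosome biogenesis genes had a median of 0.43, phosphate genes 0.41 with 13 of 13 above 0, glycolysis genes 0.23, iron genes 0.14, proteasome genes 0.11 and ribosomal protein genes 0.08. The ribosomal protein list also took in RPP1, a subunit gene of RNase P, at 0.52 ± 0.03. On the second array alone the ribosomal protein, glycolysis and proteasome medians were −0.12, −0.0475 and 0.018, and the iron median was 0.15, inside the middle 95% of random lists, against 0.30 on the first. On the first array alone 78 genes differed at least 2-fold.

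**Figure D3:**
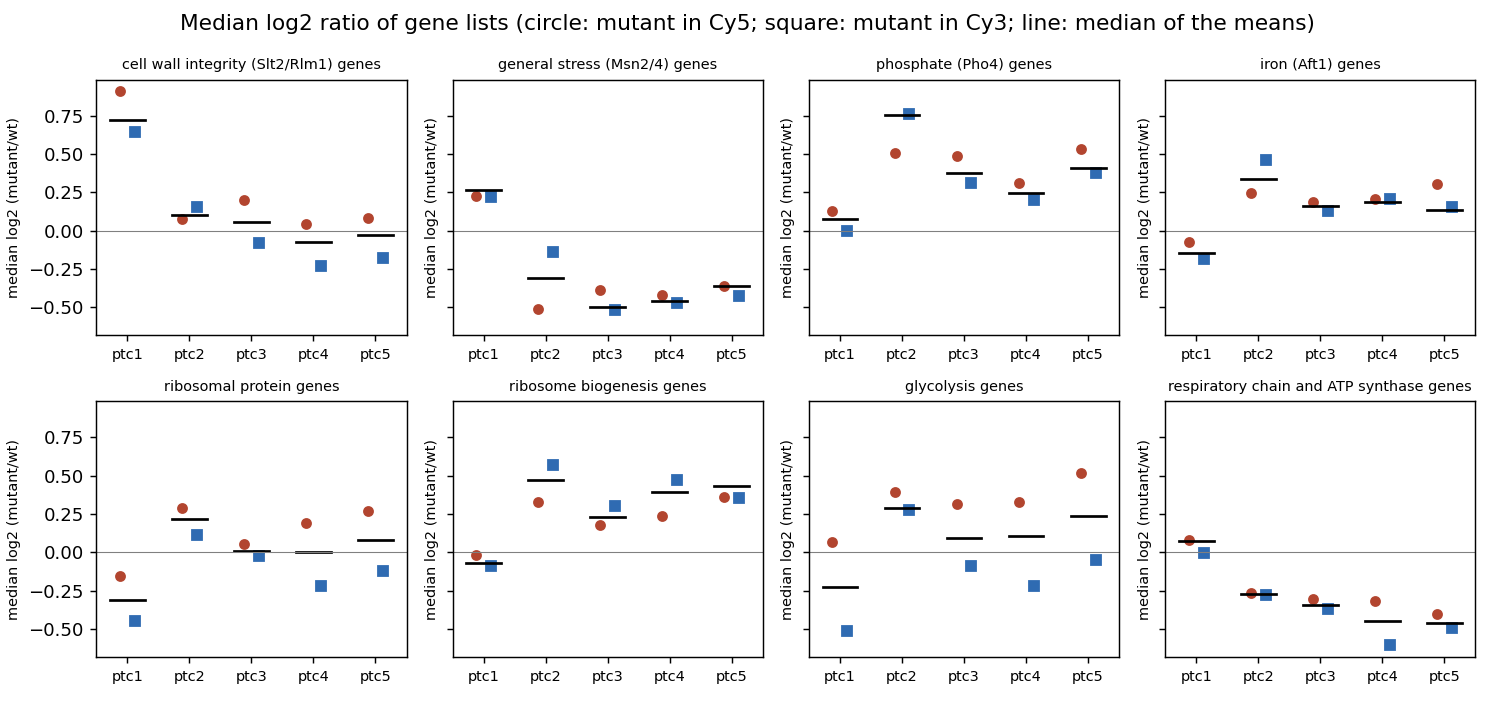
Median log2 ratio of mutant over wt (vertical axes) of 8 gene lists in each mutant (horizontal axes); circles are arrays with the mutant in Cy5, squares those with the mutant in Cy3, and the line is the median of the per-gene means, all uncentred. The general stress median is 0.26 in ptc1 and between −0.50 and −0.31 in the other 4 mutants.

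Other lists were close to 0 or varied between mutants. Over the 5 mutants, uncentred medians ran from −0.07 to 0.08 for glucose-repressed genes, from −0.09 to 0.03 for mating and pheromone response genes, from −0.02 to 0.08 for DNA damage response genes, from −0.01 to 0.16 for G2/M cell cycle genes, from −0.04 to 0.17 for amino acid biosynthesis (Gcn4) genes, from 0.0060 to 0.13 for sulfur amino acid genes, from −0.11 to 0.21 for phospholipid (Ino2/Ino4) genes and from −0.08 to 0.25 for ergosterol genes. With each array centred on its median, the ptc2 medians changed sign for glucose-repressed genes (−0.12), mating genes (−0.10) and DNA damage genes (−0.05), and also for cell wall integrity genes (−0.03 against 0.10), TCA cycle genes (−0.12 against 0.0083), pyruvate dehydrogenase genes (−0.04 against 0.09), pathway component genes (−0.06 against 0.07) and G1/S genes (−0.0005 against 0.13). Of 152 values of a list in a mutant, 58 lay outside the middle 95% of random lists. Members of a list can vary together, so this count does not measure chance. The ribosomal protein median in ptc4, for example, was 0.19 at percentile 100 on the first array and −0.22 at percentile 0 on the second. Of the marker lists, auxotrophic and deletion markers had medians from −0.16 to 0.09, led by ADE2 between −0.61 and −0.30. MATa-specific genes had medians of 0.04, 0.09 and −0.013 in ptc3, ptc4 and ptc5, sporulation genes one of 0.0090 in ptc5, and MATalpha-specific genes had at most 2 measured members, too few for a median.

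The profiles of ptc2 to ptc5 resembled each other and not that of ptc1. Across genes, which are not independent replicates, Pearson's r of the mean log2 ratios lay between 0.31 and 0.69 for the 6 pairs among ptc2 to ptc5, and between −0.10 and 0.01 for the 4 pairs with ptc1. Spearman's rho lay between 0.33 and 0.64 and between −0.11 and 0.04. Because every mutant was set against the same wt extract, unchanged mutants would also correlate. A simulation gave a mean r of 0.34 and a covariance of 0.019. It divided the observed variance beyond technical noise equally between wt and mutant extracts, true mutant effects included. These values follow from that assumption and are no measured baseline. The observed mean covariance was 0.033 among ptc2 to ptc5 and −0.0027 with ptc1. By the size rule HSP12 was higher in ptc1 and lower in each of the other 4. Part of this resemblance may come from the shared wt extract, which is a single sample and cannot be split. Between single arrays of opposite number, r lay between −0.032 and 0.33 for the 6 pairs among ptc2 to ptc5 and between −0.31 and −0.00079 for the 4 pairs with ptc1.

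With the 5 mutants taken as a set against wt, 1 gene was higher and 6 were lower (limma, adjusted p between 0.033 and 0.048). TOD6, a repressor of ribosome biogenesis genes, had a mean log2 ratio of 0.54. MTD1, ADE1, ADE17 and GCV3, of one-carbon and purine metabolism, were at −0.60, −0.51, −0.50 and −0.49, WSC4 at −0.60 and the mitochondrial ribosomal protein gene MRPS8 at −0.36. This test leaves out the spread of wt itself. In simulated data over 3606 genes it called 139 unchanged genes when the wt extract deviated as much as a mutant extract, and 0 when the wt extract did not deviate, so these 7 calls do not separate the mutants' genotypes from a chance deviation of 1 wt extract. The simulated extracts deviated as ptc2 to ptc5 differ from each other, genotype effects included, so the 139 is no measured rate of false calls. No gene passed without ptc2, ptc4 or ptc5, while 670 passed without ptc1. With arrays as samples and the replicate block 989 passed.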

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

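The results listed here differ between mutants by a test of the difference itself, each mutant against the mean of the other 4. The tests of the shared wt extract, the array numbers and the PAU genes were all chosen after the results were seen.

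In limma 62 genes were higher and 61 lower in ptc1, and 1 gene each was lower in ptc3 and ptc5, PTC3 at −7.88 and PTC5 at −2.44. The named genes of ptc1 were HSP12 at 3.70, YPS3 at 2.06, SED1 at 1.56, MSC1 at 1.38, SOL4 at 1.23, PST1 at 1.16, YOR289W at 1.16, SLT2 at 1.14, PTC1 at −1.92, SIT1 at −1.38, YML045W at −1.02, YJR026W at −0.99, FRE7 at −0.97, YJL218W at −0.88, RKI1 at −0.87 and DML1 at −0.87 on the log2 scale.

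Camera with a preset correlation called 43 lists, and none of these calls held with an estimated correlation. The repeat with the estimated correlation has 3 residual degrees of freedom and could hardly pass any list. For ptc2 to ptc5 the other 4 mutants include ptc1, so a difference can stem from ptc1 rather than from the named mutant. Against wt, uncentred cell wall integrity medians were 0.72 in ptc1 and between −0.08 and 0.10 in the other 4. General stress medians were 0.26 in ptc1 and between −0.50 and −0.31 in the other 4. The values are median log2 differences. In ptc1 they were 0.64 for cell wall integrity, 0.60 for general stress, 0.45 for respiratory chain, 0.37 for calcineurin/Crz1, 0.34 for nitrogen catabolite repressed, 0.18 for osmostress and 0.11 for TCA cycle genes. They were −0.43 for ribosome biogenesis, −0.42 for glycolysis, −0.38 for ribosomal protein, −0.38 for phosphate and −0.37 for iron genes. In ptc2, where the median over all genes was 0.13, they were 0.44 for phosphate, 0.29 for glycolysis, 0.26 for ribosomal protein and 0.26 for proteasome genes, −0.041 for osmostress genes and 0.0093 for cell wall integrity genes, whose mean was −0.026 and whose call was downward relative to other genes. In ptc3 they were −0.21 for general stress, −0.11 for proteasome and 0.055 for mating genes. In ptc4 they were −0.30 for general stress, −0.25 for cell wall integrity, −0.21 for phosphate, −0.20 for calcineurin/Crz1, −0.20 for respiratory chain, −0.19 for amino acid biosynthesis, −0.17 for TCA cycle, −0.12 for phospholipid and −0.082 for HOG and cell wall integrity pathway component genes, with 0.15 for iron and 0.12 for ribosome biogenesis genes. In ptc5 they were −0.26 for calcineurin/Crz1, −0.25 for cell wall integrity, −0.22 for type 2C phosphatase, −0.16 for respiratory chain, −0.13 for pyruvate dehydrogenase and −0.10 for DNA damage genes, with 0.18 for ribosome biogenesis, 0.15 for glycolysis, 0.13 for iron and 0.11 for ribosomal protein genes. The type 2C phosphatase and pyruvate dehydrogenase lists both hold the deleted PTC5, the only member of either that passed in limma over all genes, so their calls in ptc5 include the deletion itself.

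The first pattern is that ptc2 to ptc5 moved together against wt. A deviation of the 1 wt extract could give such shifts, and would then appear in ptc1 too. In ptc1 the medians were 0.26 for general stress genes, −0.16 for Ty frames and 0.0725 for phosphate genes. This does not exclude the wt extract, because 10 general stress genes and 12 Ty frames differed between ptc1 and the other 4 mutants, so that an opposite effect of ptc1 could hide it, and the phosphate median lay within the spread of its 2 arrays, 0.093, of the bound of 0.12. An effect shared by these 4 deletions cannot be told apart from it with 1 wt extract.

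The second pattern is that arrays of the same number resembled each other across mutants. The lowest correlation of array differences over the 10 pairs of mutants was 0.16, as a gene-specific dye bias would give. The mean r of same-number arrays of different mutants was 0.35 (SD 0.25), against 0.36 for the dye-swapped arrays of a mutant. That mean pools pairs with ptc1, between 0.011 and 0.20, and pairs among ptc2 to ptc5, between 0.18 and 0.74. The dye-swapped arrays of ptc2 to ptc5 had r of 0.49, 0.28, 0.19 and 0.34. In ptc4 and ptc5 the same-number arrays had r of 0.64 and 0.71, above the r of either mutant's own 2 arrays. A separate RNA or day for each experiment is neither shown nor excluded. Since number and dye orientation coincide, the 2 explanations cannot be told apart, and no biological explanation was tested.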

How the results depend on the processing

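Counting PAU, IMA and Ty families once was chosen after seeing the data; it gave 23 genes in ptc2 against 40. The other alternatives were planned. Causes were not tested unless stated. Counts of genes at least 2-fold different from wt (23, 40, 6, 8 and 30 in ptc1 to ptc5) became 59, 102, 21, 41 and 80 with 1.5-fold in the mean and on each array, which follows from the lower threshold. With 2-fold asked of each array they became 23 in ptc2 and 4 in ptc4. The mean of whichever arrays give a value gave 78 in ptc2 and 60 in ptc5. Leaving out each array number gave 43 to 180 in ptc2, 18 to 18 in ptc3, 8 to 31 in ptc4 and 41 to 78 in ptc5. The replicate block changed none of these 5 counts by over 1.5 times.

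Genes that set a mutant apart numbered 62 higher and 61 lower in ptc1, and 0, 1, 0 and 1 in ptc2 to ptc5. Allowing 1 array per mutant gave 56 in ptc1 and 2 in ptc2. Arrays as samples without a block gave 4 in ptc2, 5 in ptc3 and 2 in ptc5. With the replicate block they were 395, 53, 21, 2 and 21. Leaving out array numbers or mutants gave 7 to 140 in ptc1, 0 to 1 in ptc2 and 1 to 2 in ptc3. The 7 genes of the set became 0 with 1 array per mutant, 506 with arrays as samples, 989 with the replicate block and 0 to 670 with array numbers or mutants left out (670 without ptc1, 0 without ptc2, ptc4 or ptc5). The 43 list calls became 0 with an estimated correlation, a repeat with 3 residual degrees of freedom that could hardly pass any list. The median r between mutants, 0.36, became 0.11 with single arrays of opposite number.

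Of the planned list medians outside the middle 95% of random lists, those that changed sign with 1 array number left out were calcineurin/Crz1 in ptc2 (−0.057 to 0.048), ribosomal protein (−0.12 to 0.27) and glycolysis (−0.0475 to 0.51) in ptc5, and glycolysis (−0.51 to 0.067), respiratory chain (−0.0070 to 0.079) and amino acid biosynthesis (−0.037 to 0.14) in ptc1. Of the other values, 191 gene values against wt stayed within their spread and 7 moved. A single array always lies within the SD of a mutant's arrays from their mean. Leaving out an array number therefore could not move a gene value, and the 191 does not measure robustness to it. Of tested-gene values 58 kept their call and 17 lost it, and 344 list medians stayed within their spread and 106 moved. The spread of a list median was taken from the same arrays, so the 344 does not measure robustness to leaving out an array number either. Signal over background is not given with the ratios, so what it limits could not be assessed.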

Other observations

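The lists in this part, and every test but that of neighbouring genes, were chosen after seeing the data. Ty1 and Ty2 retrotransposon frames, near-identical copies that can share hybridisation, had median log2 ratios of 0.96 in ptc2 with each array centred, 0.63 in ptc3, 0.86 in ptc4 and 0.70 in ptc5, with 12 of 12 measured frames above 0 in each, and −0.16 in ptc1. On the first and second arrays alone they were 0.9975 and 0.23 in ptc3, 0.4665 and 1.21 in ptc4, and −0.011 and −0.27 in ptc1. Genes of purine and one-carbon metabolism (Bas1/Pho2) had medians below 0 in all 5 mutants, of −0.30, −0.43 centred, −0.32, −0.58 and −0.48 in ptc1 to ptc5, with 13 of 13, 12 of 14, 13 of 14, 13 of 13 and 13 of 13 members below 0 uncentred. The size rule was met only by 1 gene in ptc2, and the list was led by GCV2 at −1.06 ± 0.04 in ptc2 and −0.99 ± 0.17 in ptc4 and by MTD1 at −0.82 ± 0.02 in ptc4. With 1 wt extract this is not separated from a higher level in that extract. Heat shock factor (Hsf1) chaperone genes had a centred median of 0.30 in ptc2, led by STI1 at 1.08 ± 0.18 and SSE1 at 1.02 ± 0.49 uncentred, and medians of −0.12, 0.04, 0.05 and 0.10 in ptc1, ptc3, ptc4 and ptc5, the first of these at −0.075 on the second array alone. Isomaltase genes had too few measured members for a median; IMA3 and IMA4 were at −1.23 ± 0.09 and −1.17 ± 0.08 in ptc2 and at −1.22 ± 0.28 and −1.01 ± 0.36 in ptc5.

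Seripauperin (PAU) genes had a median of −1.11 in ptc2, −1.24 with each array centred, and −1.04 in ptc5, against −0.0010 in ptc1, 0.16 in ptc3 and −0.24 in ptc4, where the 2 arrays gave 0.37 and −0.015 in ptc3 and −0.0265 and −0.42 in ptc4. Position near chromosome ends as the whole cause is argued against by all other genes among the outermost 10 of each arm, whose median was −0.04675 in ptc5 and −0.0185 in ptc2, with a spread (MAD) of 0.24 and 0.38, although IMA3 and IMA4 among them were lower. Hypoxic genes other than PAU showed no general drop, with a median of −0.0055 and a spread of 0.23 in ptc5 and a centred median of −0.0675 in ptc2. Signal intensities were not used, so these genes may have been too low to fall further. Lower hypoxic gene expression is therefore not excluded as a cause. The 10 called PAU genes had a median correlation of 0.97 over the arrays, but they were picked for being lower, and genes regulated together would give the same. Shared hybridisation among these near-identical genes and a difference in the strains' own PAU expression both stay open.

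Whether a deletion moved the gene next to it was tested on the 2 neighbours of each deleted frame, 7 of which were measured on both arrays. The number of deletions with a neighbour at least 1.5-fold changed on both arrays was 0, which argues against a local effect of that size for the neighbours measured. The highest was DOT6 next to PTC2 at 0.44, and neither neighbour of PTC1 had both values.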
